A study of Homo sapiens with 3 samples.

How the data were processed

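RNA-seq was deposited for 3 libraries of human cells labelled MCF-7, with 1 library each for wild type, RBM39 knockdown and U2AF65 knockdown. Per the labels' protocols, cells were transfected with siRNA, total RNA was treated with DNase, polyadenylated RNA was bound to oligo(dT) beads and fragmented, and directional libraries were amplified by PCR. The labels do not say whether wild-type cells received a control siRNA. Per the submitters' processing notes TopHat2 2.0.6 and the hg19 build were used. The counting tool, the annotation, the treatment of reads with several matches and the use of strand in counting are not given in the sources used here.

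The authors deposited a table of fragment counts per gene, whole numbers that were not normalized, with gene symbols in 40205 rows. A second deposited table gives FPKM scaled by an upper quartile of each library by the authors, per its name, without the definition of that quartile. FPKM per fragment was compared between the RBM39 knockdown and wild type for the 11652 genes with at least 100 fragments in each library. For 100% of them its ratio lay within 2% of the median, so for these genes ratios between these libraries differ by scaling alone. The U2AF65 knockdown was not part of this check. Not every row follows this relation, since 569 rows in wild type, 629 in the RBM39 knockdown and 598 in the U2AF65 knockdown have 0 fragments and an FPKM above 0. Counts were used for all main values and FPKM as an alternative.

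Groups came from the sample titles and table columns were matched to them by name. The column named for U2AF2, the gene of U2AF65, was taken as the U2AF65 knockdown, and the column RMB39 was read as RBM39 with letters transposed. The column NC was taken as wild type because it names neither protein and the other columns do. Every column of values belongs to a library in the labels.

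Symbols of 28 rows had been turned into dates and name no gene; these rows were left out of library sizes and comparisons, and held 0.174% of fragments in wild type, 0.175% in the RBM39 knockdown and 0.181% in the U2AF65 knockdown. Total fragments were 54884653, 45923150 and 42004314 in the same order, of which 8.14%, 8.03% and 7.64% fell on mitochondrially encoded genes and 11.0%, 10.8% and 10.4% on the 10 largest rows. Of the symbols 28418 (70.7%) matched current or older gene names. The reference available was of another build than hg19, so no coordinates are given and its transcript lengths, exon numbers and names were used by symbol only.

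Library sizes were scaled with TMM in edgeR 4.0.16 (R 4.3.3), giving factors of 0.964 for wild type, 1.01 for the RBM39 knockdown and 1.03 for the U2AF65 knockdown. No test was run, since 1 library per group allows no estimate of spread. A gene was called when the scaled ratio was at least 2-fold, both libraries together held at least 100 fragments and the 95% exact Clopper-Pearson interval of the ratio, conditional on their sum, excluded 1. Levels carry exact Poisson intervals. A count of 0 was set to a floor of 3 fragments in that library, and no ratio was given when both counts were 3 or fewer.

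Gene lists, 33 in all, were fixed before the data were examined, covering splicing and RNA decay, the estrogen receptor axis, breast epithelial and other cell types, stress and signalling responses, the cell cycle, metabolism and translation. Each list is described by the median log2 ratio of members with at least 100 fragments and its percentile among 10000 random lists of the same size matched on expression in 50 bins. The immune list had 1 measured gene and so no median.

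Genes named in the text followed a rule fixed at the same time. Named were RBM39 and U2AF2, and for each comparison with wild type the 10 highest and 10 lowest genes past the rule, ranked by the interval bound nearest to 0, with the 5 most abundant in each direction. The comparison of both knockdowns took the 5 ranked first in each direction. Each list contributed up to 4 members past the rule, and RBM23, SRSF1, SRSF3, TRA2B, U2AF1, SF1, SF3B1, PUF60, ESR1, PGR, TFF1, GREB1, JUN and VEGFA were given whatever their value. Marker genes and list members short of the rule were chosen as examples after their values were seen, as were RPS3A and small RNAs named outside the comparisons.

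Alternatives were DESeq2 1.42.0 size factors, total fragments only, FPKM with pseudocounts of 0.1 and 1, no filter or at least 500 fragments, folds of 1.5 and 3, removal of a length or abundance trend by lowess with a span of 0.3, and intervals widened by an assumed biological coefficient of variation of 0.2. The agreement of both knockdowns was set beside 100 simulations of unchanged libraries with Poisson counting and a random division of the wild-type fragments. The agreement, trends and lists were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

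The rule was tested on simulated counts with 200 genes changed by known folds. These genes were drawn from those with at least 200 expected fragments in both libraries together. Detection of genes with 100 to 200 fragments was thus not tested. In the simulated RBM39 knockdown against wild type, over 13115 genes, it called 97.5% of genes set at 2.5-fold, 100% of those at 4-fold and 0% of those at 1.5-fold, with 1 unchanged gene called. For the U2AF65 knockdown against wild type (13065 genes) it called 100%, 100% and 0%, with 0 unchanged genes called, and for RBM39 against U2AF65 knockdown (12964 genes) 100%, 100% and 0%, with 1. The 95% intervals held the true ratio for 95.6%, 95.2% and 95.3% of genes in the same order. These simulations hold counting error alone and no spread between cultures.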

Results

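The series was made to ask how loss of RBM39 alters RNA splicing in a breast cancer cell line. It holds 3 RNA-seq libraries of poly(A)-selected RNA from cells labelled MCF-7, an estrogen receptor-positive line of luminal breast cancer cells, with 1 library per group. Wild-type cells were set beside cells transfected with siRNA against RBM39 and cells transfected with siRNA against U2AF65. RBM39 is a nuclear RNA-binding protein rich in serine and arginine that acts in splicing and as a coactivator of the estrogen receptor and AP-1. U2AF65, encoded by U2AF2, binds the polypyrimidine tract at the end of introns and recruits the U2 snRNP. The deposited tables give fragments per gene, with 54884653 in wild type, 45923150 in the RBM39 knockdown and 42004314 in the U2AF65 knockdown, so the comparisons are of gene-level abundance and splicing events were not analysed here.

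With 1 library per group no difference has a replicate check, and no p-value is given. A gene was called higher or lower when its scaled ratio was at least 2-fold on at least 100 fragments with a 95% counting interval that excluded 1. Intervals and floors cover counting error only and hold no spread between cultures, since each group has 1 library. PCR reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. Levels are given as CPM of the TMM-scaled library, and square brackets hold 95% intervals.

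Both knockdown targets were lower in the library that names them. RBM39 stood at 663 CPM in wild type, 415 in the RBM39 knockdown and 684 in the U2AF65 knockdown, so the RBM39 knockdown held 62.5% [61.4 to 63.6] of the wild-type level. U2AF2 stood at 360 CPM in wild type, 317 in the RBM39 knockdown and 172 in the U2AF65 knockdown, which was 47.9% of wild type and a log2 ratio of -1.06 [-1.10 to -1.02]. U2AF2 passed the 2-fold rule and RBM39 did not. Scaled by total fragments alone, the U2AF2 log2 ratio was -0.97 and fell short of 2-fold.

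Several marker genes did not follow the MCF-7 label, while others of the luminal list were expressed. No MCF-7 reference level was available, so expression of the latter does not speak for that line. ESR1, which encodes the estrogen receptor, was at 0.133 CPM [0.0533 to 0.273] in wild type, 0.0432 in the RBM39 knockdown and 0.0696 in the U2AF65 knockdown, from 7, 2 and 3 fragments. Its target genes PGR and TFF1 had 0 fragments in wild type and in the U2AF65 knockdown, where the upper 95% limits were 0.0699 and 0.0856 CPM. The luminal genes GATA3 and KRT19 reached at most 0.871 and 0.464 CPM, and the epithelial cadherin CDH1 at most 1.30. Other genes of the luminal list were expressed, with TBX3 at 84.4 CPM in wild type, XBP1 at 54.5, ELF3 at 47.8, MUC1 at 26.3, CLDN7 at 21.4 and FOXA1 at 10.4. Lower in wild type were EPCAM at 8.24 CPM, CLDN4 at 4.74, ERBB3 at 3.67 and SPDEF at 0.0758. CLDN3 and TFF3 had 0 fragments in every library. KRT8 and KRT18, keratins of simple epithelia, were abundant at 2586 and 2115 CPM in wild type. VIM and FN1, abundant in mesenchymal cells, were at 405 and 357 CPM in wild type, EGFR at 187 and CAV1 at 112. Of the mesenchymal list SPARC was at 111 CPM in wild type, S100A4 at 90.9, CDH2 at 70.5 and ZEB1 at 59.2. Other mesenchymal and basal genes were near 0 in wild type, with COL1A2 and COL3A1 at 0.0189 CPM each, POSTN at 0.0379, KRT5 at 0.227, KRT14 at 0.0568 and TP63 at 0.474, and THY1 had 0 fragments in every library. CDKN2A, a cell cycle inhibitor locus that MCF-7 cells are known to have lost, was at 132 CPM in wild type, 158 in the RBM39 knockdown and 136 in the U2AF65 knockdown. Immune transcripts were sparse, with only 1 of 16 listed genes at 100 fragments or more in every comparison, and PTPRC was at 0.116 CPM or less.

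**Figure D1:**
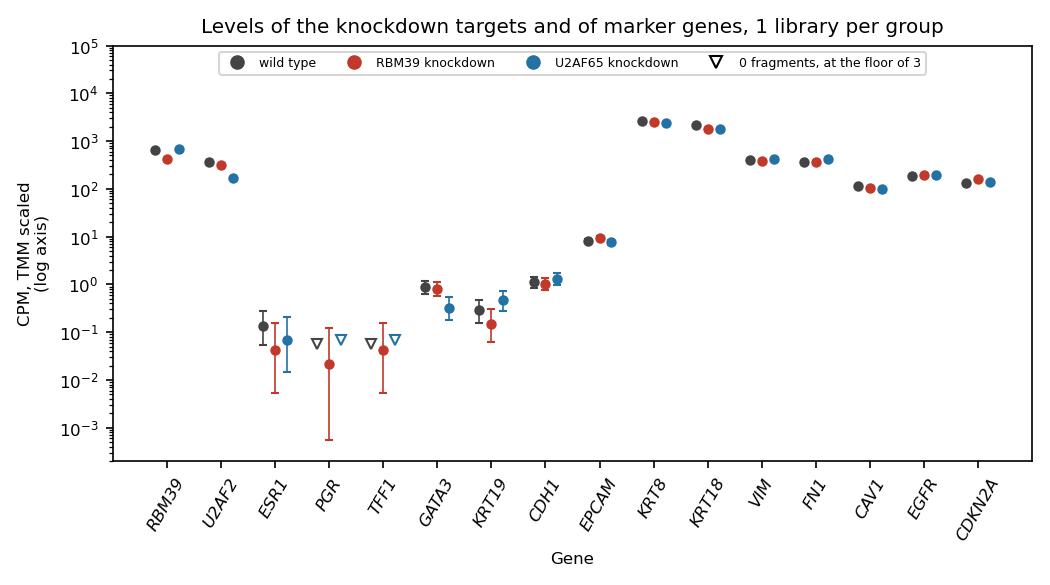
Levels of both knockdown targets and of marker genes in the 3 libraries, as TMM-scaled CPM on a log axis; points are single libraries, bars 95% Poisson intervals for counting error, and open triangles mark 0 fragments at the floor of 3. RBM39 and U2AF2 were lowest in the library that names each, and ESR1 lay at 0.133 CPM or less in every library.

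In the RBM39 knockdown, the hypoxia and glycolysis list had a median above wild type, with 23 of 30 members above 0 and 2 past the rule, and the noncoding RNAs RN7SK and RPPH1 were the lowest of the called genes. CA9, a carbonic anhydrase induced by low oxygen, was 2.87-fold higher (log2 1.52 [1.37 to 1.68]), and EGLN3, a prolyl hydroxylase of hypoxia-inducible factor, was 2.23-fold higher (log2 1.15 [0.86 to 1.45]). RN7SK, the RNA that holds the elongation factor P-TEFb inactive, was 9.40-fold lower, at 38 fragments against 407. RPPH1, the RNA of ribonuclease P, was 7.48-fold lower, at 17 fragments against 145. Both lack poly(A) tails, so their counts depend on how much such RNA passed the poly(A) selection of each library, which was not measured, and other RNAs of this kind had lower counts beside them. Transcripts of splicing factors stayed close to their wild-type levels.

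Across 13109 tested genes, 50 were higher and 26 lower by the rule, and 93.9% lay within 0.5 log2 units of equality. Higher genes made up 65.8% of those called, against 75.8% with scaling by total fragments alone. LDHC, a lactate dehydrogenase subunit of testis and sperm, had 116 fragments in the RBM39 knockdown and 3 in wild type, a 44.1-fold ratio [14.7 to 217]. CASP14, a caspase of epidermal differentiation, was 7.07-fold higher at 211 fragments against 34. SEC31B, a component of the COPII vesicle coat, was 3.37-fold higher, and PPFIA4, a liprin of cell contacts, was 2.65-fold higher. IGFBP3, which binds insulin-like growth factors, was 2.11-fold higher, at 110 CPM against 52.4.

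Rows named as pseudogenes supplied 26 of the 50 higher genes and 8 of the 26 lower genes, out of 631 such rows tested, while 17 higher and 6 lower genes were mRNAs. RPL22P1, the most abundant of the called rows, was 2.44-fold higher at 636 CPM against 261. Of 8 tested copies of the ribosomal protein gene RPS3A, 5 were higher by the rule, 7 were above 0 and 1, RPS3AP20, was below 0 at a log2 ratio of -0.77. Those named by rank or abundance were RPS3AP47 at 3.30-fold, RPS3AP26 at 2.86-fold, RPS3AP21 at 2.59-fold and RPS3AP6 at 2.18-fold, beside RPL7P9 at 2.36-fold. RPS3A itself had a log2 ratio of 0.29. Pseudogene rows share sequence with their parent genes, and how the authors' counting split such reads is not given in the sources used here, so these values are uncertain. Among lower rows were RN7SL2 (log2 -1.46 [-1.59 to -1.34]) and RN7SL1 (-1.35 [-1.52 to -1.19]), RNAs of the signal recognition particle, with their copy RN7SL5P at -1.17. RNA18SP2, a copy of the 18S ribosomal RNA gene, was at 42.9% of wild type, and the mitochondrial tRNA gene TRNF at 40.3%. The lower pseudogene rows included RPL26P36 at 44.4%, NPM1P50 at 40.7% and RPS26P10 at 37.7% of wild type.

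Of the preset gene lists, 4 of the 32 with a median had one outside the central 95% of 10000 random lists matched on expression. If genes varied independently, 1.6 would be expected by chance. Members of a list can vary together between cultures, which the random lists do not hold. More than 1.6 lists outside is thus not by itself a sign of a knockdown effect. The hypoxia and glycolysis list had a median log2 ratio of 0.18 at percentile 100. Of its 30 measured members 23 were above 0 and 2, CA9 and EGLN3, passed the rule. NDRG1 was at 0.86, PFKFB4 at 0.76 and BNIP3 at 0.57, while the glycolytic enzymes PKM and TPI1 were at -0.15 and -0.11. The list did not move evenly, with SLC2A1 at 68.2 CPM against 66.7 in wild type, PGK1 at 532 against 524 and PFKFB3 at 21.7 against 24.8. Cholesterol synthesis genes had a median of 0.10 (percentile 99.6), with 20 of 25 above 0, INSIG1 at 0.70 and HMGCS1 at 0.47, and none past the rule. The p53 target list, at 0.09 (percentile 97.1), and the integrated stress response list, at 0.06 (percentile 97.0), lay just inside the range, and the latter was outside it in 2 of 8 settings. Nuclear receptors and their coregulators had a median of -0.19 (percentile 0.34), with 12 of 16 below 0, among them the coregulators PELP1 at -0.49 and NCOR1 at -0.31. Cytosolic ribosomal protein genes had a median of 0.02 where matched random lists lay lower, from -0.15 to -0.04; with upper-quartile FPKM the median was -0.01, so its sign depends on the scaling.

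Splicing lists lay within the random range, with nonsense-mediated decay factors just inside its lower edge at percentile 2.59. Median log2 ratios were -0.11 for the U2 snRNP and splice site recognition, -0.04 for SR and SR-related proteins, -0.07 for hnRNP proteins, -0.02 for SR protein kinases, -0.06 for RBM proteins and -0.16 for nonsense-mediated decay factors, with no member past the rule. Only the U2 snRNP and decay medians kept their sign in every setting tried. RBM23, the closest paralog of RBM39, had a log2 ratio of -0.07, SRSF1 of -0.12, TRA2B of -0.10, U2AF1 of -0.14, SF1 of -0.11, SRSF3 of 0.04, PUF60 of 0.06 and SF3B1, the branch site factor, of 0.24 [0.21 to 0.27]. In the estrogen receptor and AP-1 axes GREB1 was at -0.76 [-1.24 to -0.29] on 58 fragments against 112, JUN at -0.11 and VEGFA at 0.04, and ESR1 at -1.62 [-4.92 to 0.77]; PGR and TFF1 had too few fragments for a ratio. The 23 measured estrogen receptor target genes had a median of 0.04 (percentile 79.4), in cells where ESR1 gave at most 7 fragments. That median ran from -0.0032 to 0.11 over the settings tried.

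In the U2AF65 knockdown the medians of the hypoxia and p53 target lists were above wild type and that of the interferon list below, though few members passed the rule, at 4 of 30, 0 of 26 and 2 of 29. CA9 was 3.04-fold higher (log2 1.61 [1.45 to 1.76]), EGLN3 was 2.76-fold higher, PFKFB4, which controls glycolytic flux, 2.21-fold, and NDRG1, a gene induced by hypoxia and stress, 2.15-fold. LOX, which cross-links collagen, was 2.58-fold higher, and CASP14 was 8.62-fold higher at 239 fragments against 34. The interferon-induced genes MX2 and PSMB9 were at 39.8% and 48.9% of wild type. RN7SK and RPPH1, with the same limit of poly(A) selection, were 4.15-fold and 3.29-fold lower.

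By the rule 32 of 13081 tested genes were higher and 15 lower, of which 19 and 8 were mRNAs, and 10 and 1 were rows named as pseudogenes. Higher genes were 68.1% of those called, against 82.5% with scaling by total fragments alone. PPFIA4 was 2.93-fold higher, SPAG4, a protein of the nuclear envelope, 2.70-fold, IGFBP3 2.12-fold and VLDLR, a lipoprotein receptor counted among genes of the integrated stress response, 2.04-fold. RPS3AP47 was 2.46-fold higher, RPL7P9 2.17-fold, RPS3AP26 2.13-fold and RPL22P1 2.00-fold, with the same uncertainty over shared reads. PRPF40B, a splicing factor associated with the U1 snRNP, was at 47.5% of wild type (log2 -1.07 [-1.29 to -0.86]). SNORD3A, the U3 RNA of ribosomal RNA processing, was at 35.0% and SCARNA7, a guide RNA of Cajal bodies, at 48.5%. The uncharacterised LOC100996433 was at 39.4%, the pseudogene row HMGB1P4 at 38.4% and the axonemal dynein gene DNAH2 at a log2 ratio of -1.25 [-1.84 to -0.69]. Scaling by total fragments alone left PRPF40B, SCARNA7 and PSMB9 short of 2-fold, at log2 ratios of -0.98, -0.95 and -0.94, and the deposited FPKM left RPL22P1 and VLDLR short at 0.96 and 0.98; with a pseudocount of 1 DNAH2 was short as well, at -0.76.

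Here 5 of the 32 lists lay outside the central 95% of random lists, with 1.6 expected only if genes varied independently. The hypoxia and glycolysis list had a median log2 ratio of 0.31 at percentile 100, with 25 of 30 members above 0 and 4 past the rule; P4HA1, a collagen prolyl hydroxylase, was at 0.79 and BNIP3 at 0.68. The p53 target list had a median of 0.20 (percentile 99.98), with 22 of 26 members above 0 and none past the rule, CDKN1A being at 0.71 and BTG2 at 0.36. The interferon list had a median of -0.18 (percentile 0.02), with 23 of 29 members below 0, 2 past the rule and ISG15 at -0.50. Cholesterol synthesis had a median of 0.07 (percentile 97.8), which was inside the range at percentile 97.3 once an abundance trend was removed. The nuclear-encoded respiratory chain had a median of -0.12 (percentile 0.95), with UQCRH at -0.56, and was inside at percentile 3.66 once a length trend was removed. Lists just inside the range were mesenchymal genes at 0.10 (percentile 97.3), outside in 2 of 8 settings, and ribosomal proteins at -0.06 (percentile 96.9), outside in 3 of 8 and of either sign by scaling. Endoplasmic reticulum chaperones, at 0.03, were outside in 1 of 8.

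Medians of the splicing lists lay within the random range here too, at -0.12 for the U2 snRNP and splice site recognition, -0.09 for SR and SR-related proteins, -0.16 for hnRNP proteins, 0.12 for SR protein kinases, -0.10 for RBM proteins and -0.08 for decay factors. With an abundance trend removed the RBM list was outside the range, at percentile 1.94, and the SR and decay medians changed sign with the scaling. U2AF1, the small subunit partner of U2AF65, had a log2 ratio of -0.25 [-0.28 to -0.21], and SF1, which binds the branch site beside U2AF65, of 0.34 [0.31 to 0.37]. SF3B1 was at 0.09, PUF60 at 0.10 and SRSF1 at -0.13. RBM23, SRSF3 and TRA2B, at -0.08, -0.06 and -0.09, changed sign with scaling by total fragments. GREB1 was at -0.12 [-0.55 to 0.30], not distinguishable from wild type at this depth, JUN at -0.19 and VEGFA at 0.16. ESR1 was at -0.93 [-3.51 to 1.20], and PGR and TFF1 had 0 fragments in both libraries.

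**Figure D2:**
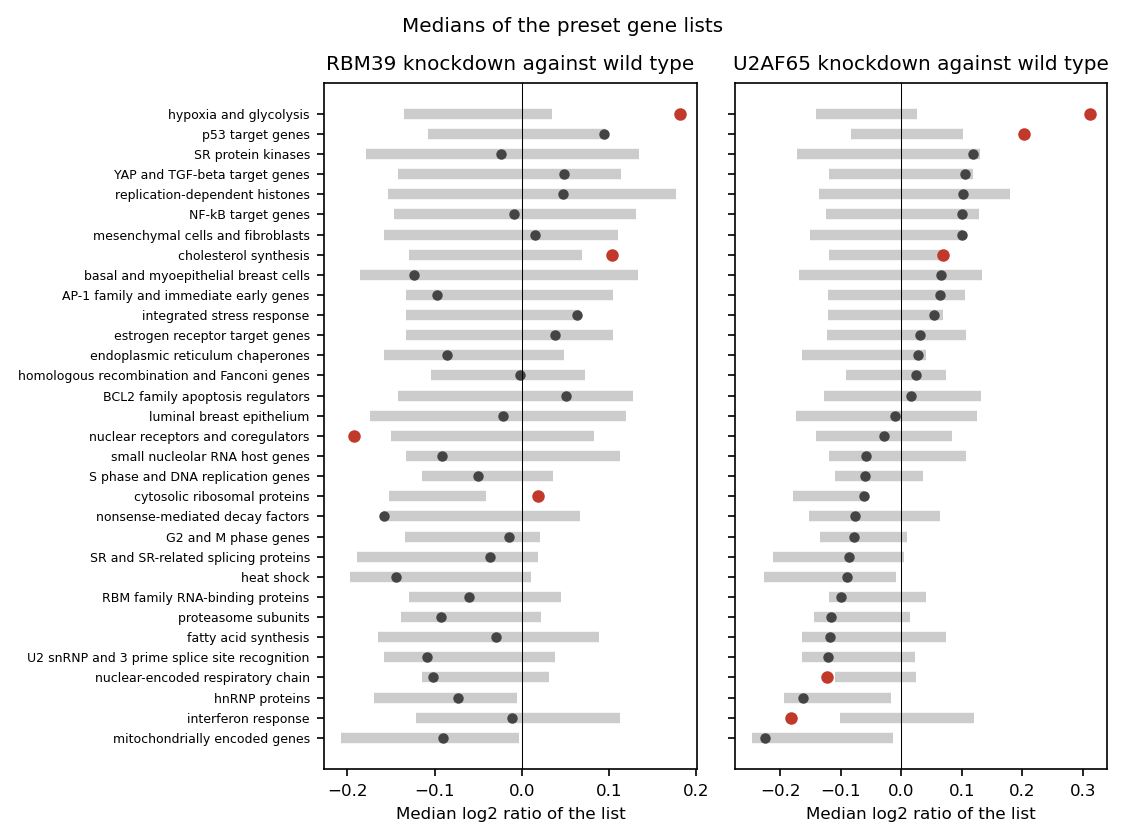
Median log2 ratio of each preset gene list in the RBM39 knockdown (left) and the U2AF65 knockdown (right) against wild type; points are medians over members with at least 100 fragments, grey bars the central 95% of 10000 random lists matched on expression, and red points lie outside the bar. The hypoxia and glycolysis list lay farthest above its bar in both, at 0.18 and 0.31. Horizontal axes differ between the panels, and several medians near 0 change sign with the scaling, among them the ribosomal list on the left.

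Genes that differed from wild type tended to differ the same way in both knockdowns, which a shared wild-type library favours by itself. CASP14, CA9, PPFIA4, EGLN3 and IGFBP3 were higher in both by the rule, and RN7SK, RPPH1, SCARNA7 and SNORD3A were lower in both. Over 13029 genes tested in both comparisons, 18 were higher in both and 8 lower in both, against 0.107 and 0.0299 for independent lists, and 0 went opposite ways. Across genes, which are not independent replicates, the log2 ratios correlated with a Pearson r of 0.710 and a covariance of 0.0493. Unchanged libraries simulated against the same wild-type library gave an r of 0.469, a covariance of 0.00542 and 0.01 genes higher in both. Each comparison uses the same 1 wild-type library, so part or all of the excess may come from that shared control. Neither the independent lists nor the simulation holds spread between cultures, so they cannot bound that share. With the wild-type fragments divided at random between the comparisons, r was 0.608 and the covariance 0.0423, with 21 genes higher and 4 lower in both. That division removes shared counting error but not the shared culture. Nor does it remove siRNA transfection, which both knockdowns share and which wild-type cells may not have had.

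**Figure D3:**
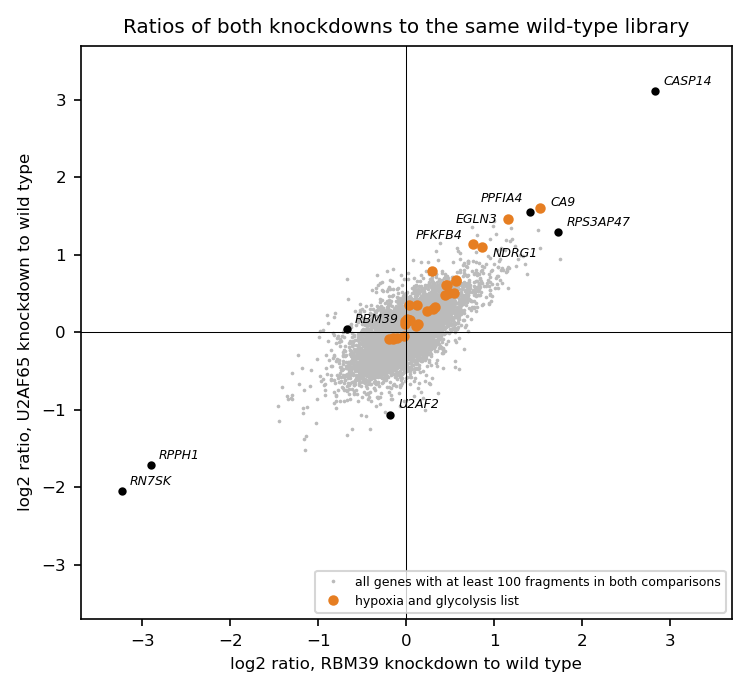
Log2 ratio to wild type in the RBM39 knockdown (horizontal) and the U2AF65 knockdown (vertical) for genes with at least 100 fragments in both comparisons; grey points are genes, orange points the hypoxia and glycolysis list and black points other genes named in the text. The points spread along the diagonal (r 0.710), with CASP14 at the upper right and RN7SK and RPPH1 at the lower left; each ratio uses the same wild-type library. LDHC lies outside the plot because it had under 100 fragments in the U2AF65 comparison.

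The knockdowns differed less from each other than either did from wild type, and few genes set them apart. LDHC had 116 fragments in the RBM39 knockdown and 0 in the U2AF65 knockdown. With that 0 set to the floor of 3 fragments the ratio was 36.0-fold. The lower 95% limit, computed from 116 against 0 fragments, was 28.8-fold. RNFT1, a RING finger gene, was at 47.0% of its level in the U2AF65 knockdown (log2 -1.09 [-1.33 to -0.85]). The interferon list had a median log2 ratio of 0.19 (percentile 99.99), with 20 of 28 members above 0 and PSMB9 at 0.80, and the hypoxia list a median of -0.11 at percentile 0, with 24 of 30 below 0; no member of either list passed the rule.

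Of 12972 tested genes 8 were higher and 9 lower in the RBM39 knockdown, with 5 mRNAs each way, and 97.3% lay within 0.5 log2 units. Higher genes made up 47.1% of those called, against 57.1% with the deposited FPKM and a pseudocount of 1. PGM2L1, a phosphoglucomutase family member, was 2.21-fold higher on 88 fragments against 37, and ARHGDIB, an inhibitor of Rho GTPase cycling, 2.31-fold higher on 72 against 29. The noncoding rows LOC101929005 and LOC100421296 were 2.37-fold and 2.11-fold higher. C5orf56 was at 39.0% of its U2AF65 knockdown level, FLJ44342 at 48.0%, LOC101929155 at 49.3% and LOC81691 at 49.7%. With FPKM and that pseudocount PGM2L1 was at a log2 ratio of 0.82, LOC81691 at -0.98, FLJ44342 at -0.97 and LOC101929155 at -0.96, all short of 2-fold. RBM39 had a log2 ratio of -0.72 and U2AF2 of 0.88.

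Among the 32 lists 10 lay outside the central 95% of random lists, with 1.6 expected only if genes varied independently. Below the range, beside hypoxia, were endoplasmic reticulum chaperones (median -0.10), p53 targets (-0.10) and nuclear receptors with their coregulators (-0.10). Above the range, beside interferon genes, were the U2 snRNP list (0.10), RBM proteins (0.08), genes of the G2 and M phases (0.08), ribosomal proteins (0.08) and mitochondrially encoded genes (0.12). SNRPA1, a U2 snRNP protein, was at 0.44 and the RNA helicase DDX46 at 0.32, while SF1 was at -0.45. The p53, nuclear receptor, ribosomal and mitochondrial lists moved inside the range with a length trend removed, at percentiles of 2.70, 5.08, 88.5 and 95.4. The mitochondrial list was outside in only 6 of 8 settings, and each of the others in 7 of 8. The hnRNP list, at 0.07, and the AP-1 list, at -0.07, were inside but moved outside in 2 and 1 of 8 settings. Of the fixed genes, SF3B1 was at 0.15, U2AF1 at 0.11, SRSF3 at 0.10, JUN at 0.08, PUF60 at -0.04, VEGFA at -0.12 and GREB1 at -0.64 [-1.15 to -0.14], while RBM23 was at 0.00, SRSF1 at 0.00 and TRA2B at -0.01. ESR1, PGR and TFF1 had 3 fragments or fewer in each knockdown, so no ratio is given.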

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

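Tests of depth, of a minority of other cells and of another cell line for the marker levels, and of library scaling and the wild-type culture for the hypoxia list, were chosen after the result was seen. Values outside the comparisons stood out in both deposited tables. Rows whose symbols had become dates, which name no gene, held 95703 fragments in wild type, 80513 in the RBM39 knockdown and 75997 in the U2AF65 knockdown. Rows with 0 fragments but an FPKM above 0 numbered 569, 629 and 598 in the same order, with highest FPKM values of 3.67, 9.02 and 3.64.

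In all 3 libraries, some marker genes departed from the MCF-7 label, with ESR1, GATA3 and KRT19 near absent and VIM, EGFR and CDKN2A abundant. Displaced gene names across the rows as a whole were argued against by a Spearman rho of 0.789 between implied and annotated transcript lengths over 11121 mRNA rows. Of 16 luminal rows 15 lay within 2-fold of their annotated lengths, against 76.3% when rows were drawn at random. For the luminal rows themselves this check thus says little. Low depth was argued against by an upper limit for ESR1 of 0.273 CPM or less in every library. A minority of other cells among MCF-7 cells would leave ESR1, GATA3 and KRT19 high, but the highest level of these 3 was 0.871 CPM; other luminal genes, such as TBX3 at 84.4 CPM and XBP1 at 54.5 in wild type, were expressed and were not part of this test. CDKN2A, which MCF-7 cells have lost, was at 132 CPM or more in every library. With ESR1, GATA3 and KRT19 near absent, this argues against MCF-7 cells as the main source of the libraries. Which other line was used cannot be told from these values. No biological explanation was tested. The ratios between the libraries do not depend on the label of the line, but reading them as changes in MCF-7 cells does.

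The hypoxia and glycolysis list had a median above wild type in both knockdowns. Library scaling was argued against as the whole cause by a median of 0.15 or more over 4 scalings, and a length or abundance trend by a percentile of 100 with either trend removed in both knockdowns. A wild-type culture with low levels of these genes, for instance from lower density or fresher medium, may equally give the pattern. With 1 wild-type library it cannot be told apart from an effect of both knockdowns. The labels do not say whether wild-type cells received a control siRNA, so transfection itself cannot be told apart either. The knockdowns also differed from each other, with a median of -0.11 for RBM39 against U2AF65. An effect of either knockdown stays open and untested.

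Rows named as pseudogenes made up 26 of the 50 genes higher in the RBM39 knockdown and 10 of the 32 higher in the U2AF65 knockdown. Log2 ratios of such rows with a parent gene had SDs of 0.48 and 0.41 in that order, against 0.24 in both for mRNA rows. Their medians were 0.12 and 0.10. A wider spread and a raised median by themselves put more rows past a fixed 2-fold rule. Genomic DNA was argued against by olfactory receptor rows, which held a mean of 0.18 fragments or fewer in every library. Reads shared with parent genes could account for the rows, but a parent at least 10 times higher was common to 31 of 34 rows past the rule and 563 of 680 others with at least 100 fragments, so it does not single out the called rows. The Spearman rho of pseudogene and parent fragments was 0.212 across 5891 rows, and the parents' median log2 ratios were 0.09 and 0.03 against 1.16 and 1.19 for the higher rows, so a plain spill of parent reads in a fixed share would not give these ratios. A placement of shared reads that differed between libraries stays open.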

How the results depend on the processing

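Settings with mRNA rows only, random lists drawn from mRNA rows and an abundance trend removed from the lists were chosen after the results were seen. No paired analysis was possible because each group has 1 library, and no library could be left out. A count was taken as unmoved within 1.5 times the reported count, a log2 ratio inside its reported 95% interval and r within 0.05. By these tolerances 78 values that answer a comparison were unmoved and 41 moved, and for named genes 480 were unmoved and 72 moved; none that was called changed sign. The number of lists outside the random range was 4 to 5 for RBM39 against wild type, 5 to 7 for U2AF65 against wild type and 8 to 10 between the knockdowns. Counts of called genes are given as higher and lower for RBM39 against wild type, U2AF65 against wild type and RBM39 against U2AF65, in that order, where 50 and 26, 32 and 15, and 8 and 9 were reported. With no filter on fragments they were 240 and 217, 227 and 141, and 112 and 161, by construction from rows with few fragments. With at least 500 fragments they were 21 and 5, 13 and 2, and 1 and 2. At 3-fold they were 4 and 2, 2 and 2, and 1 and 0, and at 1.5-fold 296 and 219, 265 and 180, and 79 and 119. With mRNA rows only they were 17 and 6, 19 and 8, and 5 and 5. Intervals widened by the assumed coefficient of variation of 0.2 left the shares of higher genes unchanged at 65.8%, 68.1% and 47.1%. A ratio of at least 2-fold mostly lies beyond that widening. This setting could thus hardly move the counts, and its unmoved values say little. With upper-quartile FPKM and a pseudocount of 1, RBM39 against U2AF65 gave 4 and 3, so higher genes were 57.1% of those called. The same FPKM with a pseudocount of 0.1 gave 46.7%, near the 47.1% of the main setting. A larger pseudocount draws ratios of rows with low FPKM toward equality by construction. Scaling by total fragments gave log2 ratios to wild type of -0.61 for RBM39 and -0.11 for U2AF2 in the RBM39 knockdown, and of 0.14 for RBM39 and -0.97 for U2AF2 in the U2AF65 knockdown, since it shifts every ratio of a comparison alike. With FPKM and a pseudocount of 0.1, RBM39 was at -0.71 in its own knockdown and 0.01 (0.0068) in the U2AF65 knockdown. The median of all tested genes moved alike, from -0.016 to -0.046 in the RBM39 knockdown and from -0.0056 to -0.043 in the U2AF65 knockdown. The move of RBM39 is thus that of the scaling. Genes past the rule in both knockdowns numbered 26, against 9 with at least 500 fragments and 10 with mRNA rows only, and r was 0.710, against 0.608 with the wild-type fragments divided. Depth limits genes such as ESR1, whose 7 fragments or fewer leave wide intervals on the ratios to wild type and no ratio between the knockdowns.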

Other observations

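The test of single-exon genes was written before its result was seen, and the small RNAs were chosen after their values were seen.

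Several small structured RNAs without poly(A) tails, which oligo(dT) selection should mostly remove, had lower values in the knockdowns, though no list of them was set in advance. RMRP, the RNA of ribonuclease MRP, had 25 fragments in wild type and 6 in each knockdown, with log2 ratios of -1.87 [-3.45 to -0.55] and -1.77 [-3.34 to -0.45] for RBM39 and U2AF65. RN7SL1, RN7SL2 and RN7SL3 of the signal recognition particle had log2 ratios of -1.35, -1.46 and -1.45 in the RBM39 knockdown and of -0.82, -0.95 and -1.14 in the U2AF65 knockdown. SNORD3A was at -1.15 and -1.51 and SCARNA7 at -1.18 and -1.04. The vault RNA VTRNA1-2 had 9, 1 and 2 fragments in wild type, RBM39 knockdown and U2AF65 knockdown, and the telomerase RNA TERC 28, 12 and 13. For the U2AF65 knockdown the intervals of VTRNA1-2 [-5.13 to 0.40] and TERC [-1.89 to 0.18] included 0. SCARNA2 had log2 ratios of -0.10 [-1.55 to 1.31] and -0.58 [-2.30 to 0.98], RNU4-2 was at 0.29 [-2.13 to 2.72] in the U2AF65 knockdown, and the Y RNAs RNY1, RNY3, RNY4 and RNY5 had 0 fragments in every library. Not every short RNA was lower, since 33 measured small nucleolar RNA rows, most of them within introns of host genes, had median log2 ratios of 0.16 and 0.08, and 16 replication-dependent histone genes had medians of 0.05 and 0.10.

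Nuclear-retained long RNAs differed less. MALAT1 was at -0.28 and -0.20, and NEAT1 at -0.21 in the RBM39 knockdown and 0.17 in the U2AF65 knockdown. The snRNA rows together held 548, 141 and 185 fragments in wild type, RBM39 knockdown and U2AF65 knockdown, with 407, 38 and 80 of them on RN7SK.

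A hypothesis was that loss of a splicing factor could lower transcripts with introns relative to intronless ones. Single-exon coding genes would then stand above random coding genes matched on expression. Their median log2 ratio was -0.04 over 175 genes in the RBM39 knockdown and -0.03 over 173 genes in the U2AF65 knockdown, at percentiles of 7.36 and 7.45, so this was not borne out at the level of gene totals.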
